A study of Homo sapiens with 4 samples.

How the data were processed

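RNA from human umbilical vein endothelial cells was measured on 4 two-colour Agilent arrays of design Agilent-014850. Per the labels, Cy3 carried the negative control mimic and Cy5 the miR-181b mimic on every array, the RNA was extracted with Trizol, and labelled cRNA was made with a Quick Amp kit. The amount hybridised and the origin of the replicates were not given in the sources used here. The arrays share 1 slide and 1 scan, so no batch was tested.

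Per the file headers, the scanner tables were made with Agilent Feature Extraction 10.5.1.1 and hold, for each spot, the mean signal and the median local background as intensity. Per the file headers, they also hold processed signals (background subtracted, detrended and dye normalized by linear and lowess curves) as intensity and their log10 ratio. The deposited table of the series and the authors' other table per array hold log10 ratios of Cy5 over Cy3, which was checked against the scanner tables (99.66% to 99.78% of the probes within 1e-04). The authors' tables per array also give each probe's intensity per dye and a p-value within 1 array, which was not used here. The software of the tables per array was not given in the sources used here.

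The mean signals were corrected for local background with normexp (offset 50) and normalized within each array by loess (span 0.3) with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Of 45015 spots, 1639 control spots were left out, as were spots that the scanner software marked as outliers (97 to 185 per array), and 0 spots were saturated. Spots of the same probe were averaged. A probe was tested when it was well above background in at least 1 channel on at least 3 of 4 arrays (28377 probes). Of 41000 probes, 23958 were matched to a current gene by accession, 2755 by symbol and 1032 by synonym, and 13255 were not matched. The reference gene table gave names, and positions came from the array annotation on hg18. XIST and genes of chromosome Y (75 probes) were left out of every test. A gene was represented by its brightest tested probe, which gave 13597 genes of 17843 on the array.

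Each gene's mean log2 ratio over 4 arrays was tested against 0 with limma (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. SD is the spread over the 4 arrays. Each array pairs both RNAs, and fits without that pairing are among the alternatives. An exact sign-flip test on 4 arrays cannot give a two-sided p under 0.125. On simulated log2 ratios with 200 changed genes of 13597, the limma fit and adjustment recovered 7.35% of changes of 0.25 and 57.6% of changes of 0.5. They recovered 90.9% of changes of 1, and 1.90% of the calls were wrong. The simulated noise was independent between arrays and genes. Background correction, normalization, the filter and the choice of probes were not simulated. A far larger share of genes was called in the data (20.1%), so these rates need not hold there.

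The 25 gene lists, the named genes and the alternatives were fixed before the data were examined. Named were KPNA4, VCAM1, SELE and ICAM1, then the 8 genes with the largest rise and the 8 with the largest fall. These needed an adjusted p under 0.05, 1 sign on all 4 arrays, a gene symbol that is not a clone or locus name, and both channels well above background on all 4 arrays. Then came up to 4 members per list with the largest change among those past the threshold. Lists with at least 5 tested genes were compared with all other genes by camera (preset correlation 0.01, adjusted over lists), by camera with an estimated correlation, and by fry, which asks whether a list's genes move on balance to 1 side and compares them with no other genes. The lists covered leukocyte adhesion molecules, TNF and NF-kB induced genes, chemokines and cytokines, NF-kB components, importins, reported miR-181 targets, endothelial identity, interferon response, S phase, mitosis, coagulation, BCL2 family, p53 targets, unfolded protein response, cholesterol biosynthesis, hypoxia, immediate early genes, extracellular matrix, Notch, microRNA machinery and 5 sets of cell type markers.

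The alternatives covered the background correction, the normalization, the filter on dim probes, the variance model, array weights, separate channels, the threshold, the unit counted, the probes of a gene, the authors' tables, the set test and leaving out each array. Leaving out 14 spots of array 3 whose local background was over 2 times the array's median was added after the data were examined and after the counts with and without them had been seen. The values given first use all spots, as fixed beforehand. Figures were drawn with python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.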

Results

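Messenger RNA was measured on 4 arrays, each of which set RNA from human umbilical vein endothelial cells given a miR-181b mimic (Cy5) against RNA from such cells given a negative control mimic (Cy3). A mimic is a synthetic double-stranded RNA that raises the level of 1 microRNA. Per the labels, primary cells at passage 3 received 10 nM of mimic, grew for 36 h and were then exposed to TNF-α, an inflammatory cytokine, at 10 ng/ml for 4 h. Each array is 1 replicate with 1 log2 ratio per gene (miR-181b over control, n = 4). The labels call the arrays biological replicates and do not say whether they came from separate cultures or donors. Of 41000 probes, 27012 to 28353 per array were well above background in Cy3 and 25455 to 29185 in Cy5, and the number of arrays limits the precision. The dyes were not swapped on any array, so a dye effect on a gene was not separated from the effect of the mimic.

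The comparison asks which transcripts differ in TNF-α treated endothelial cells once miR-181b is raised. VCAM1, SELE and ICAM1, adhesion molecules by which endothelial cells capture leukocytes, were lower with miR-181b on 4 of 4 arrays. VCAM1, a ligand of leukocyte integrins, fell 2.12-fold (log2 ratio -1.09 ± 0.19, SD, n = 4, adjusted p = 0.00172). SELE (E-selectin), on which leukocytes roll, fell 1.70-fold (-0.76 ± 0.24, adjusted p = 0.00425), and ICAM1, another integrin ligand, fell 1.46-fold (-0.54 ± 0.17, adjusted p = 0.00538). KPNA4 (importin α3), which carries NF-kB into the nucleus and is a target of miR-181b known from the study, fell 1.12-fold (-0.16 ± 0.03, adjusted p = 0.0431). On hg18, the build of the array's annotation, the KPNA4 probe lies on chromosome 3 from 161700737 to 161700796. The VCAM1 probe lies on chromosome 1 from 100976371 to 100976430, the SELE probe on chromosome 1 from 167958673 to 167958732, and the ICAM1 probe on chromosome 19 from 10257298 to 10257358. Which exon or untranslated region each probe covers was not analysed here. With median centring in place of the intensity-dependent loess curve, no gene of these 4 passed and, relative to the median gene, KPNA4 stood at 0.25, ICAM1 at 0.03, SELE at -0.06 and VCAM1 at -0.61. KPNA4 also missed the threshold without replicate 1, 2 or 4 (adjusted p from 0.136 to 0.187) and with the deposited ratios (adjusted p = 0.0868). Over all alternatives its adjusted p ranged from 0.0109 to 0.764. With 14 spots of array 3 left out, a choice made after seeing the data, KPNA4 stood at -0.22, VCAM1 at -1.09, SELE at -0.72 and ICAM1 at -0.52.

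The rises past the threshold that were largest by the fixed rule included a chemokine receptor, a vasodilator peptide and a cytokine. CXCR4, the receptor of CXCL12, rose 2.38-fold (log2 ratio 1.25 ± 0.27, SD, n = 4), ADM (adrenomedullin) rose 2.26-fold (1.18 ± 0.17) and TGFB2 rose 2.11-fold (1.08 ± 0.15). PCDH17, a protocadherin, rose by 1.04 on the log2 scale, ASPH, an aspartyl hydroxylase, by 1.02, FSTL5 by 1.00, LYPD1 by 0.94 and PKIA, an inhibitor of protein kinase A, by 0.92. FSTL5 stood at 0.08 on array 3 and at 1.00 to 1.47 on the others. The fall that was largest was that of PLPP3, a phosphatase of bioactive lipids such as lysophosphatidic acid, which fell 2.85-fold (-1.51 ± 0.07, adjusted p = 6.2e-05). SRGN, the proteoglycan serglycin, fell by 1.06 (SD 0.13), and PLAU, the urokinase that activates plasminogen, fell by 1.01 (SD 0.05). PUDP fell by 1.12 (SD 0.54), MERTK, a receptor kinase for the uptake of dying cells, fell by 1.09 (SD 0.61), NPR1, a receptor of natriuretic peptides, fell by 1.06 (SD 0.61) and SLC66A2 fell by 1.04 (SD 0.21). On array 3 the log2 ratio was -0.37 for PUDP, -0.19 for MERTK and -0.15 for NPR1. Adjusted p for these 15 further genes, beside VCAM1, lay between 6.2e-05 and 0.0215, and each had its sign on 4 of 4 arrays, as the naming rule required. On hg18, the PLPP3 probe (PPAP2B on the array) lies on chromosome 1 from 56733428 to 56733487, the CXCR4 probe on chromosome 2 from 136588423 to 136588482, the ADM probe on chromosome 11 from 10285356 to 10285415 and the TGFB2 probe on chromosome 1 from 216683872 to 216683931.

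**Figure D1:**
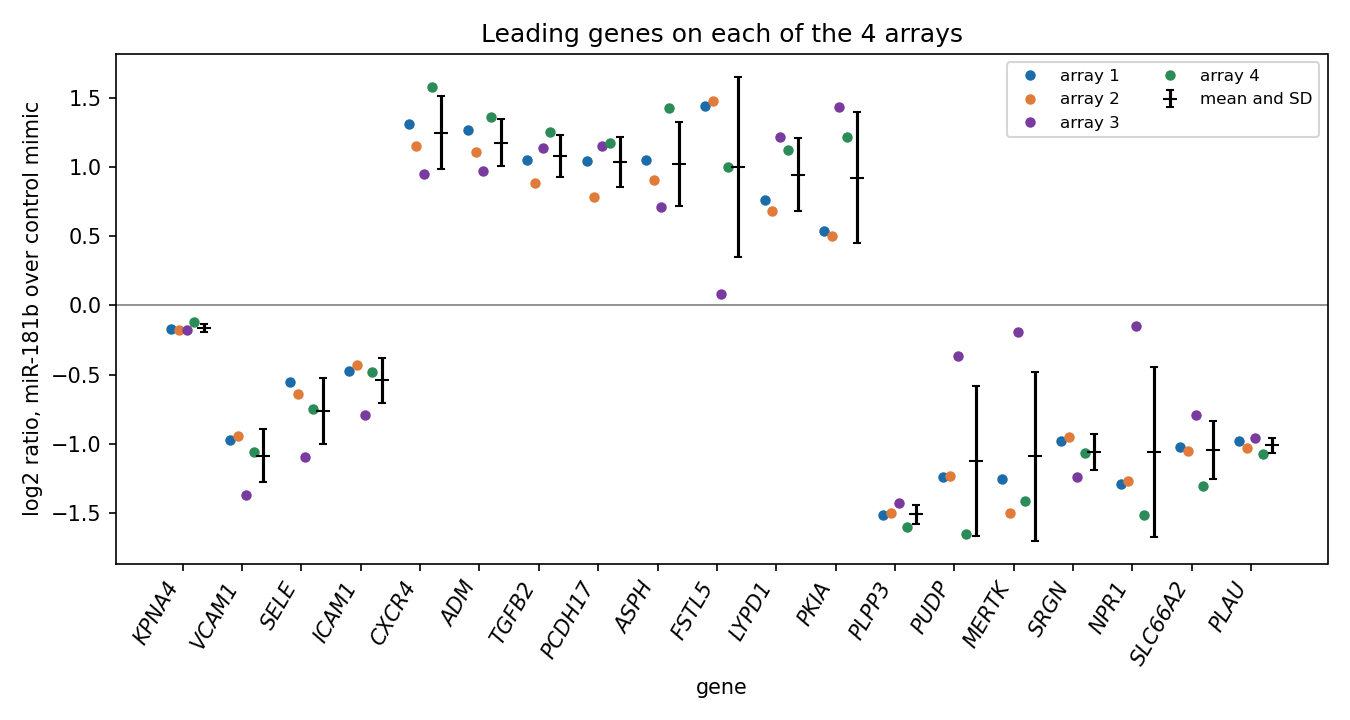
Log2 ratio of miR-181b over control mimic (vertical axis) for KPNA4, VCAM1, SELE and ICAM1, then the genes with the largest rise and fall, with 1 point per array and the mean with its SD over 4 arrays. PLPP3 lies between -1.60 and -1.43, while array 3 sits near 0 for FSTL5 (0.08), MERTK (-0.19) and NPR1 (-0.15). With median centring, which leaves in any curve of the log ratio with intensity, KPNA4 and ICAM1 stood above the median gene (0.25 and 0.03). With the scanner's signals, which carry their own lowess curve, they stood at -0.18 and -0.53.

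Across 13597 genes tested with limma, 1760 were higher with miR-181b and 971 lower (20.1% of the genes), and 2685 of them had 4 of 4 arrays on the side of the call. Most of the changes were small in this fit, with 5 genes higher and 10 lower by at least 2-fold, and 47 higher and 87 lower by at least 1.5-fold. Sizes were counted in this fit alone and may differ in others. In it, array 3 had a slope of 0.42 on the log2 ratio of the other arrays, which had slopes of 0.84 to 1.07. The background fit of array 3 was drawn off by 14 spots with extreme local background, and leaving these out, a choice made after the counts with and without them had been seen, gave 3065 genes higher and 2958 lower. The counts were 133 and 100 without replicate 1, 226 and 131 without replicate 2, 2790 and 2664 without replicate 3, 98 and 89 without replicate 4, and, by limma with median centring, 0 and 0 (4423 and 1613 at an unadjusted p under 0.05), or 13 and 3941 relative to the median gene.

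TNF and NF-kB induced genes were lower as a group in a test against all other genes (camera, preset correlation, adjusted p = 9.04e-11), a call that was not kept at adjusted p = 0.698 with an estimated correlation, nor by fry (adjusted p = 0.126). Of 68 tested, 31 fell, 6 rose and 31 did not pass (34 lower and 6 higher adjusted over the list alone), with a median log2 ratio of -0.21. With the 14 spots left out, 43 fell and 8 rose, with a median of -0.29. PLAU fell as above, and CXCL1, a chemokine for neutrophils, fell by 0.93 (SD 0.21). Outside the fixed naming rule, CCL2, a further chemokine of this list, rose by 0.55 (SD 0.13) with all spots. NFKBIA (-0.08), TNFAIP3 (-0.11) and CXCL8 (-0.06) were among the 31 that did not pass. The list's median was -0.02 on array 3 and -0.32 to -0.25 on the others, and it was -0.01 relative to the median gene with median centring or no normalization, where the call was lost (adjusted p = 0.203 and 0.495).

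Of 23 leukocyte adhesion molecules, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.10 that turned to 0.15 above the median gene with median centring or no normalization. CX3CL1, a membrane-bound chemokine, fell by 0.70 (SD 0.10), while CD34, a sialomucin of vascular endothelium, rose by 0.54 (SD 0.27). The list's adjusted p was 0.00138, and adjusted p = 0.643 with an estimated correlation. The call was also lost with median centring, no normalization and scaling between arrays (adjusted p = 0.187, 0.457 and 0.0521), and with the 14 spots left out 11 fell and 1 rose. Of 37 components of NF-kB signalling, 9 fell and 28 did not pass (9 lower and 1 higher adjusted over the list alone), with a median of -0.08 that turned to 0.08 above the median gene with median centring or no normalization. These lists share members with the TNF and NF-kB induced genes, so they are not independent findings. Shared members that fell were VCAM1, SELE, ICAM1 and CX3CL1 among adhesion molecules, and RELB, TNIP1, NFKB1, NFKB2 and CYLD among NF-kB components. RBCK1, a subunit of the linear ubiquitin ligase, fell by 0.44 (SD 0.20), and RELB, an NF-kB subunit, fell by 0.36 (SD 0.10) but stood 0.27 above the median gene with median centring. The list's adjusted p was 0.00128, and adjusted p = 0.698 with an estimated correlation. The call was also lost by fry and with median centring, no normalization and scaling between arrays (adjusted p = 0.197, 0.321, 0.863 and 0.0521). With the 14 spots left out, 18 components of NF-kB signalling fell and 3 rose, with a median of -0.14. With all spots, the median was 0.02 on array 3 and -0.15 to -0.09 on the others.

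Of 35 chemokines and cytokines, 11 fell and 8 rose (13 and 9 adjusted over the list alone), with a median of -0.11. Of those that fell, CXCL1, CXCL2, CXCL6, CX3CL1, CCL20, CSF1, CSF2 and LIF are also in the list of TNF and NF-kB induced genes. CCL20, a chemokine for lymphocytes and dendritic cells, fell by 0.87 (SD 0.36), while IL1B, the cytokine interleukin-1β, rose by 0.78 (SD 0.46) with 0.08 on array 3. The list's adjusted p was 0.0493, and adjusted p = 0.698 with an estimated correlation, and the call was also lost without replicate 4 (adjusted p = 0.0588) and with the 14 spots left out (adjusted p = 0.112, with 16 lower and 10 higher). It was lost as well with the scanner's signals (adjusted p = 0.166), with median centring (0.916), no normalization (0.186) and scaling between arrays (0.0544), and by fry (0.498).

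Genes of mitosis and of S phase were higher as groups by camera at a preset correlation (adjusted p = 7.02e-07 and 0.0015). Neither call was kept, at adjusted p = 0.698 with an estimated correlation for each and adjusted p = 0.148 and 0.185 by fry, and that of S phase was also lost with scaling between arrays (adjusted p = 0.0544). Of 44 mitosis genes, 23 rose and 21 did not pass (29 higher adjusted over the list alone), with a median of 0.25. MAD2L1, a spindle checkpoint protein, rose by 0.51 (SD 0.27), AURKA, a mitotic kinase, by 0.44 (SD 0.21), ANLN, an organiser of the contractile ring, by 0.41 (SD 0.16) and CCNA2, a cyclin, by 0.37 (SD 0.14). Of 42 genes of S phase and DNA replication, 13 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.18. GINS2, part of the replicative helicase, rose by 0.46 (SD 0.24) and RRM2, a subunit of ribonucleotide reductase, by 0.46 (SD 0.26). With the 14 spots left out, 29 mitosis genes rose and 1 fell, and 20 genes of S phase rose and 4 fell. The medians were then smaller, at 0.21 and 0.13, with camera adjusted p = 1.19e-05 and 0.00418. In that fit 3065 of all 13597 genes were higher, against 1760 with all spots, so the larger counts are not particular to these lists. With all spots, the medians on array 3 were 0.37 for mitosis and 0.31 for S phase, against at most 0.28 and 0.13 on the others.

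Of 29 reported targets of miR-181, 8 fell and 5 rose (10 and 5 adjusted over the list alone), with a median of -0.07. DUSP6, a phosphatase that restrains ERK, fell by 0.63 (SD 0.10), HIPK2, a nuclear kinase, by 0.56 (SD 0.18), CBX7, a Polycomb protein, by 0.58 (SD 0.36) and CTDSPL, a phosphatase, by 0.54 (SD 0.33). On array 3, CBX7 stood at -0.04 and CTDSPL at -0.08. The list holds KPNA4, which is known from the study and so is not independent evidence of its direction. The list's adjusted p was 0.0493, and adjusted p = 0.698 with an estimated correlation, and the call was also lost without replicate 2 or 3 and with the 14 spots left out (adjusted p = 0.112, with 13 lower and 6 higher). It was lost as well with the scanner's signals (adjusted p = 0.186), with median centring (0.938) and no normalization (0.301), and by fry (0.185). Of 34 importins and other nuclear transport genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), and with the 14 spots left out 8 rose and 5 fell. NUP153, a nuclear pore protein, rose by 0.49 (SD 0.06), while TNPO1, an import receptor, fell by 0.35 (SD 0.01) but stood 0.14 above the median gene with median centring. This list did not pass (adjusted p = 0.421).

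Of 378 tested genes of the ZNF gene family, whose repeated zinc finger coding sequence is known to match miR-181, 24 rose and 23 fell. The family's median, relative to that of all genes, was -0.03, and it did not pass (camera gave a p of 0.0849, and a p of 0.569 with an estimated correlation). It passed without replicate 1 (-0.04, a p of 0.0283), without replicate 2 (-0.04, a p of 0.0405), with scaling between arrays (-0.07), and with median centring or no normalization (-0.42). Median centring and no normalization leave in, by their construction, any curve of the log ratio with intensity. A pass under them was therefore not separated from such a curve.

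Genes of coagulation, fibrinolysis and vascular tone moved both ways. Of 28 tested, 9 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of -0.14 and adjusted p = 0.0259, and adjusted p = 0.698 with an estimated correlation. This call was also lost with the mean over a gene's probes (adjusted p = 0.0503), with median centring and no normalization (adjusted p = 0.709 and 0.863) and by fry (adjusted p = 0.197), and with the 14 spots left out 14 fell and 6 rose. Beside PLAU and ADM above, PTGS2, the inducible cyclooxygenase, fell by 0.75 (SD 0.34). PLAU and PTGS2 are also in the list of TNF and NF-kB induced genes. Among 39 genes of endothelial identity, 9 fell and 8 rose (11 and 11 adjusted over the list alone), and with the 14 spots left out 16 fell and 10 rose. ESM1 (endocan) fell by 0.94 (SD 0.32), S1PR1, a receptor of sphingosine-1-phosphate, by 0.91 (SD 0.27) and CLDN5, a tight junction protein, by 0.63 (SD 0.17), while THBD, the receptor of thrombin, rose by 0.55 (SD 0.21). This list did not pass (adjusted p = 0.282).

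**Figure D2:**
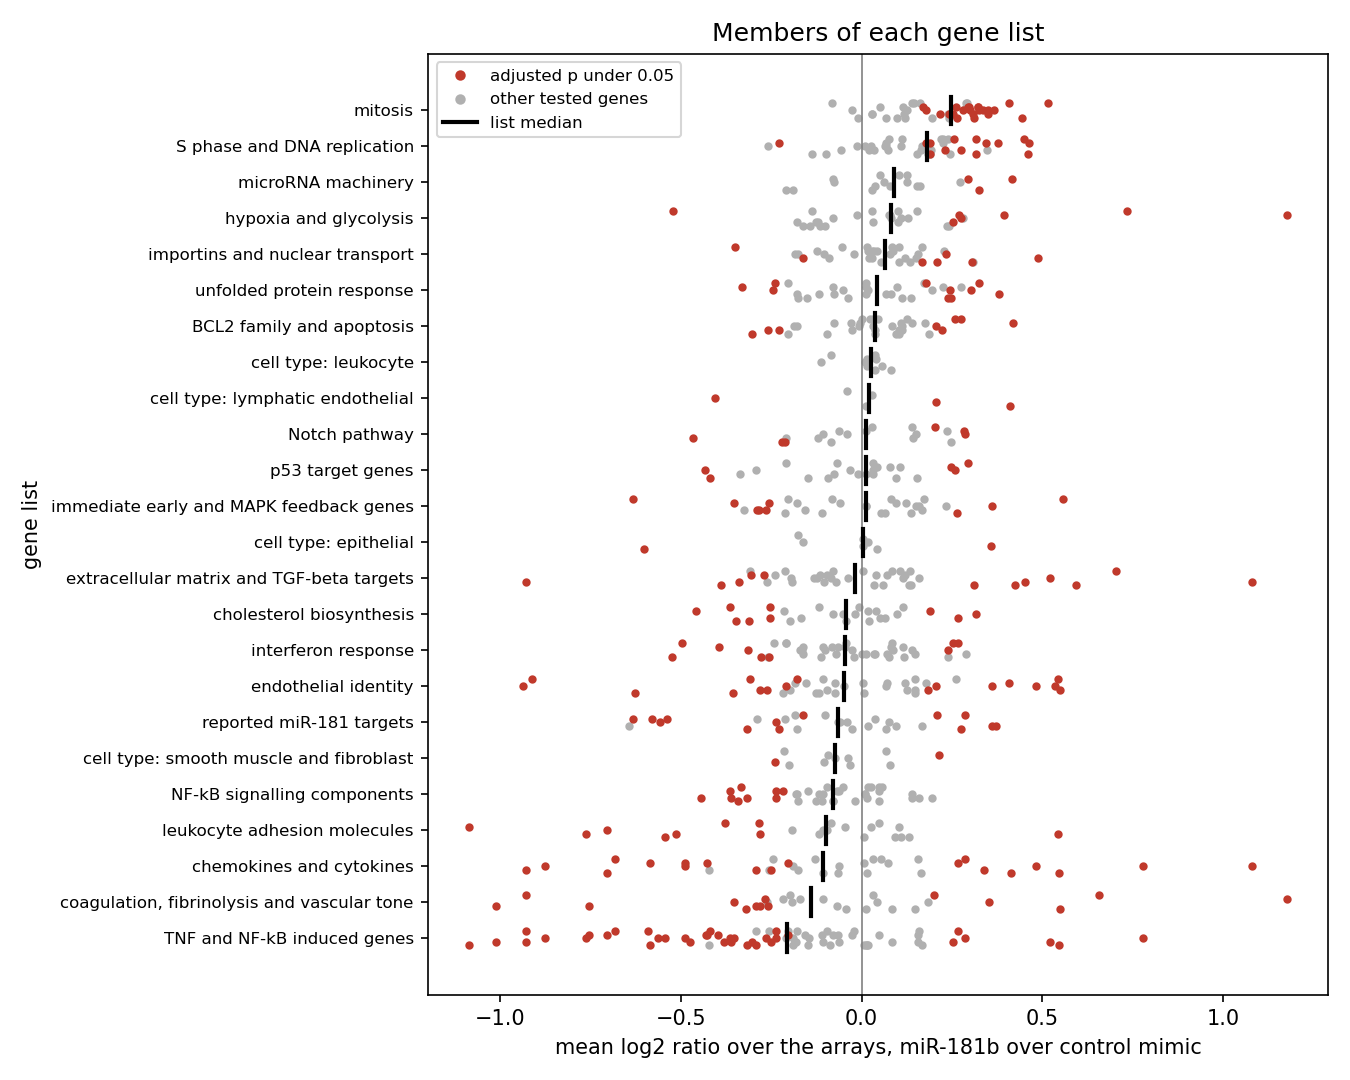
Mean log2 ratio of miR-181b over control mimic over 4 arrays (horizontal axis) for the tested genes of each list with at least 5 of them (vertical axis), red where the adjusted p is under 0.05, with a bar at the list's median. The TNF and NF-kB induced genes have the lowest median (-0.21) and the mitosis genes the highest (0.25). With median centring or no normalization, the medians of the adhesion molecules and of the NF-kB components turned to 0.15 and 0.08 above the median gene.

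Markers of other cell types moved both ways or did not pass. Of 11 tested markers of smooth muscle and fibroblasts, SMTN (smoothelin) fell by 0.24 and TAGLN (transgelin) rose by 0.21, the latter standing at -0.03 relative to the median gene with median centring (1 and 1 adjusted over the list alone). With the 14 spots left out, 4 of these markers fell and 1 rose. By limma, 0 of 10 leukocyte markers passed, and 0 were under an unadjusted p of 0.05. Of 8 epithelial markers, 1 fell and 1 rose (2 and 1 adjusted over the list alone, and 3 and 1 with the 14 spots left out), and KRT19, a keratin, fell by 0.60 (SD 0.28). Of 6 lymphatic endothelial markers, SEMA3D rose by 0.41, LYVE1, a receptor of hyaluronan, rose by 0.21 and FLT4, the receptor of VEGF-C, fell by 0.40 (2 and 1 adjusted over the list alone). Of 8 erythroid markers, 2 were tested and 0 passed by limma or were under an unadjusted p of 0.05. The adjusted p of the cell type lists lay between 0.159 and 0.867.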

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

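The test of the background fit of array 3 was chosen after the result was seen. In 124 sets of 4 values, 1 per array (named genes, list medians and array measures), 19 had an array whose gap to its nearest neighbour took up more of the range than Dixon's critical value for 4 values allows, where chance gives about 1 in 20 (6.2), and array 3 was the far one in 15 of the 19. That rate holds for independent sets that were not selected. These sets share the same arrays, and most are genes named for their change on them, so 6.2 is only a rough guide.

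Array 3 lay far from the others for ICAM1 (gap over range 0.867), IL1B (0.956), CBX7 (0.835), THBD (0.835), DHX58 (0.839), DDB2 (0.838), XBP1 (0.941), SREBF2 (0.932), SPRY1 (0.865), NOTCH4 (0.839), ADAM10 (0.872) and MFNG (0.841). It also lay apart in the median of chemokines and cytokines (0.844), in the number of probes well above background in Cy5 (0.860, with 25455 against 28663 to 29185) and in the share of genes called by the other 3 arrays that had the same sign on it (0.944, with 77.3% of 5452 genes against 98.7% to 100% of 224 to 395). Among the 224 genes with the lowest p in each such fit, array 3 had 97.3% and the others 98.7% to 100%. These shares lie near the upper limit on every array, so they do not tell whether that gap followed from the number of genes called. Over the genes called by the other 3 arrays, array 3 had a slope of 0.42 on their log2 ratio, against 0.84 to 1.07 for the others. Array 4 lay apart for KPNA4 (0.894, with -0.12 against -0.18 to -0.17), MMP1 (0.898, with 0.93 against 0.46 to 0.51) and the median of leukocyte markers (0.854). Array 1 lay apart in the median Cy5 signal (0.842).

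The pattern of array 3 was set against its background fit. This array had 14 spots with a local background over 2 times the median, up to 197034 in Cy3, and its fitted Cy5 background offset was -259.0 with them and -13.8 without, against -15.8 to -13.8 on the others. Of 116 named genes and lists, 13 had array 3 far out with all spots and 2 had it with the 14 spots left out, which is consistent with the background fit as a candidate explanation for most of them. The correlation of array 3 with the others, across genes, which are not independent replicates, was 0.326 to 0.415 with all spots and 0.618 to 0.749 without them. No biological explanation was tested, since the labels give none for array 3.

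Probes without a current gene name stood outside the comparison of genes, and 513 of 7445 passed the threshold, 375 higher and 138 lower with miR-181b.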

How the results depend on the processing

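The alternative that left out 14 spots of array 3, and the estimated correlation for the ZNF family, were chosen after seeing the data. VCAM1, SELE and ICAM1 kept their direction and passed with another offset, no background correction, the scanner's signals, the authors' tables, other filters, array weights and each array left out (without 1 replicate, VCAM1 -1.13 to -0.99, SELE -0.83 to -0.65, ICAM1 -0.58 to -0.46). KPNA4 kept its direction there (-0.18 to -0.16 without 1 replicate) but missed the threshold at offset 16 (-0.16, adjusted p = 0.0768), with the scanner's signals (-0.18) and both authors' tables (-0.18 and -0.18), with trend and robust eBayes (-0.16), with separate channels (-0.16) and without replicate 1, 2 or 4, where its adjusted p ranged from 0.0768 to 0.187. The cause was not tested.

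Median centring and no normalization left the median of all genes at 0.70 and 1.13, against 0.03 with loess, and values and adjusted p under them are relative to that median. They differ by a constant per array, so relative values are the same in both by construction and are not separate evidence, though adjusted p differs. They gave, alike, KPNA4 0.25, VCAM1 -0.61, SELE -0.059, ICAM1 0.032, TNIP1 0.11, RELB 0.27, TAB2 0.082, TNPO1 0.14, ISG20 0.019, CFLAR 0.17, XBP1 0.15, HMGCS1 0.029, SPRY1 -0.027, DLL1 -0.68, MFNG 0.36, TAGLN -0.034, the ZNF gene family -0.42, adhesion molecules 0.15 and NF-kB components 0.082. As they stood, KPNA4, VCAM1, SELE and ICAM1 were 0.94, 0.09, 0.64 and 0.73 with median centring and 1.38, 0.53, 1.07 and 1.17 with no normalization. Dye intensity curves are left in by both, by their construction. By limma, with the median left in, median centring gave 0 genes higher and 0 lower (4423 and 1613 at an unadjusted p under 0.05), and no normalization 8868 and 0 (9230 and 0). Relative to the median gene, median centring gave 13 and 3941 and no normalization 0 and 0. Loess with scaling between arrays left the median of all genes at 0.10 and gave 0 and 0 (717 and 907), with KPNA4 -0.40, VCAM1 -2.99, SELE -2.34, ICAM1 -1.68 (each at adjusted p = 0.514), the ZNF gene family -0.070 and 4 lists. The scaled VCAM1 value lay outside its loess values on the 4 arrays (-1.37 to -0.94). Sizes after scaling are therefore not comparable with those of the other settings. The cause was not tested.

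An ordinary one-sample statistic per gene gave 10 higher and 8 lower, with KPNA4 -0.16, VCAM1 -1.09, SELE -0.76 and ICAM1 -0.54 past no threshold (adjusted p from 0.0839 to 0.129), since 4 arrays leave each gene few degrees of freedom. The numbers of genes higher with miR-181b and genes lower with miR-181b were 2812 and 3202 with no background correction, 2508 and 2516 with the scanner's signals, 3110 and 2606 with array weights (0.332 for array 3), 802 and 474 with separate channels, 5 and 10 by at least 2-fold, 320 and 190 at adjusted p under 0.01, 2513 and 2507 with the series table and 2515 and 2510 with the tables per array. Without 1 replicate they ranged from 98 to 2790 higher and from 89 to 2664 lower. With the 14 spots left out they were 3065 and 2958, of which 1734 and 970 were shared with the fit to all spots. The share of changed genes that were higher was 64.4% with all spots, 50.9% without the 14 and 49.9% with the scanner's signals. The ZNF gene family ranged from -0.042 to -0.023 without 1 replicate and passed without replicate 1 or 2. Of 8 lists called by camera, 0 held with an estimated correlation (1 of 24 at an unadjusted p under 0.05) and 1 by fry (adhesion molecules, adjusted p = 0.0184). Between 7 and 8 lists were called without 1 replicate. For 88 other named genes under 20 alternatives, 1206 of 1760 pairs kept direction and threshold (8 of them under median centring, relative to the median gene), 530 kept direction alone and 24 turned. The 24 were 12 under median centring and 12 under no normalization, whose relative values are the same by construction. Not run were leaving out saturated probes, since there were 0, and the planned tests of miR-181 sites in 3' untranslated regions and coding sequence with their alternatives, since the genome sequence was not among the sources used here. Signal over background limits the dim genes. Array 3 had the fewest probes well above background (27012 in Cy3 and 25455 in Cy5). Its median background was 21 in Cy3 and 57 in Cy5, against 19 to 21 and 54.5 to 57 on the others. The background fit of array 3, described above, is a further limit there.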

Other observations

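Among the tests in this part, those of further probes and the seed search within probe sequences were chosen after the result or the files had been seen. Genes of the extracellular matrix and TGF-β response moved both ways, with 7 of 40 higher and 5 lower (7 and 5 adjusted over the list alone), and 9 higher and 12 lower with the 14 spots of array 3 left out. COL8A1, a short-chain collagen, rose by 0.70 (SD 0.30) and MMP1, a collagenase, by 0.59 (SD 0.22). Of 30 genes of hypoxia and glycolysis, 6 rose and 1 fell (8 and 1 adjusted over the list alone, 11 and 5 without the 14 spots), with SLC2A1, a glucose transporter, up by 0.74 (SD 0.16) and LDHA, lactate dehydrogenase, up by 0.39 (SD 0.07), while SLC2A3, another glucose transporter, fell by 0.52 (SD 0.32). Neither list passed (adjusted p = 0.444 for matrix and 0.417 for hypoxia). Of 25 genes of cholesterol synthesis, 6 fell and 3 rose (8 and 3 adjusted over the list alone, 11 and 3 without the 14 spots), with SQLE, an epoxidase, down (log2 ratio -0.46, SD 0.09), SREBF2, the pathway's regulator, at -0.36 and EBP, an isomerase, at 0.32. The list missed the threshold (adjusted p = 0.0574) and passed with the 14 spots of array 3 left out (0.0474). Of 42 interferon response genes, 6 fell and 3 rose (7 and 3 adjusted over the list alone, 15 and 6 without the 14 spots), among them the RNA sensors DHX58 (-0.53, SD 0.28) and IFIH1 (-0.31, SD 0.22), with adjusted p = 0.063 for the list.

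Of 18 genes of the microRNA machinery, 3 rose and 15 did not pass (3 adjusted over the list alone), while without the 14 spots 5 rose and 4 fell. Those that rose with all spots were TNRC6A, a partner of Argonaute, by 0.41 (SD 0.16), CNOT7, a deadenylase, by 0.33 (SD 0.10) and TARBP2, a partner of Dicer, by 0.29 (SD 0.04). Of 19 Notch genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone, 5 and 8 without the 14 spots), with NOTCH4 at -0.47 (SD 0.21) and the protease ADAM10 at 0.28 (SD 0.11). Of 32 genes of the unfolded protein response, 7 rose and 3 fell (9 and 6 adjusted over the list alone, 9 and 10 without the 14 spots), with ASNS at 0.38 and XBP1 at -0.33 (0.15 above the median gene with median centring or no normalization). Of 35 BCL2 family and apoptosis genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone, 6 and 8 without the 14 spots), with CYCS (cytochrome c) at 0.42 and CFLAR at -0.26 (0.17 above the median gene with median centring or no normalization). Of 23 p53 targets, 3 rose and 2 fell (4 and 4 adjusted over the list alone, 4 and 8 without the 14 spots), with PLK3 at -0.43 and GADD45A at 0.29. Of 30 immediate early genes, 6 fell and 3 rose (7 and 4 adjusted over the list alone, 10 and 7 without the 14 spots), with EGR1 at -0.35 and DUSP5 at 0.36. The adjusted p of these lists lay between 0.261 and 0.824. Median and mean were positive or mixed while the test leaned down for p53 targets (median 0.01, mean -0.03), immediate early genes (0.01 and -0.03), Notch genes (0.01 and 0.01), matrix genes (-0.02 and 0.02), leukocyte markers (0.03 and 0.01) and epithelial markers (0.003 and -0.06), since the test is relative to all genes, whose median was 0.03. Without the 14 spots, the medians of p53 targets, immediate early genes and Notch genes were -0.05, -0.03 and -0.10.

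The genes past the threshold were set against a dye bias of single probes and against base composition. Among 1198 changed genes with a further probe that shares no 12 bases with the first, 82.2% of further probes had the same sign, against at most 55.3% in 1000 draws of random probes, which argues against a bias set by each probe's own sequence. Base counts of the probes accounted for 0.058% to 1.20% of the variance of the log ratios per array, and after regression on them the number of changed genes was 100.2% of that before (2662 called the same way in both), which argues against a linear effect of base composition as the whole cause. A bias of dye shared by a whole transcript stays open, since the dyes were not swapped. The 8 sign-flip splits of the arrays are too few for a share under 0.05: the real split gave 1760 and 971 genes (1 of 8 with as many, in each direction), and the highest other gave 0 by limma, with 2677 genes at an unadjusted p under 0.05 when array 3 alone was turned.

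A hypothesis was that pairing with the miR-181b seed lowers transcripts, tested on the 60-base probe sequences since transcripts were not among the sources used here. Of 11625 words of 7 bases, the match TGAATGT ranked 27 (136 genes) and GAATGTA ranked 4 (80 genes) from the lowest z score of the log2 ratio adjusted for base counts and brightness, the higher of the 2 percentiles being 0.232, and it lay between 0.086 and 0.429 under 6 alternatives. Of 180 genes with a match, 23 (12.8%) fell, against 7.07% of 13417 genes without, 19 rose, and the difference in mean log2 ratio was -0.04, -0.07, -0.05 and -0.08 on the 4 arrays. These values go with seed pairing in part of the lower genes, which stays a hypothesis tested on these data alone. The search within probes was chosen after the files had been seen. A dye bias tied to these words stays open, since the dyes were not swapped. The word CAGGGGA, which is no seed match, was lowest of all with all spots and all arrays (z score -5.11 against -4.96 for GAATGTA). CAGGGGA was also lowest without replicate 2 (-4.90 against -4.75) and with the spots of extreme local background left out (-5.22 against -5.07). Other words that are no seed match were lowest without replicate 3 (GGGGAGG, -5.38 against -4.88) and without replicate 4 (TTTGGGG, -5.18 against -4.50). GAATGTA was lowest without replicate 1 (-5.32) and with the scanner's signals (-5.03).

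Lower TNF and NF-kB induced genes and higher mitosis genes were set against a dye curve left by brightness and against a bias of single probes. The TNF list's median lay at percentile 0 and the mitosis list's at percentile 100 of 10000 random lists of the same brightness, which argues against a brightness curve alone. Over further probes of the genes, the TNF list had a median of -0.26 (22 genes, 20 with the sign of the first probe) and the mitosis list 0.18 (10 genes, 9 with the sign), which argues against a bias of single probes. The effect of the mimic and a bias of dye shared by whole transcripts stay open for both lists.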
